A study of Homo sapiens with 24 samples.

How the data were processed

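The cells were MCF7, a human breast cancer line that expresses the estrogen receptor. Per the labels' protocols, they were kept without hormones for 24 h, transfected with RAD21 or control siRNA, kept without hormones for 48 h more, and treated with 100 nM estradiol or with ethanol vehicle for 3 h or 6 h. Per the labels' protocols, RNA from 3 independent experiments per time point was hybridised to Affymetrix PrimeView arrays. Cells were harvested at both times, so arrays of 3 h and 6 h may come from the same cultures. The deposited values are log2 intensities of probe sets, and per the submitters' processing notes they were made with RMA, whose version and settings were not given. The values themselves show 2 distributions, one per time point, with a median difference of 0.914 between sorted values, so the time points appear to have been normalized apart. Time point and array series cannot be told apart, and a gene's level was not compared between 3 h and 6 h. Raw intensities were not analysed here.

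Of 49395 probe sets, 102 were controls, 44988 had 1 gene, 1832 had several and 2473 had none in the platform annotation. Probe sets with 1 gene were used, of which 44961 matched the reference gene table by gene identifier, and 0 symbols needed an update. Of the 18132 genes, 11734 had several probe sets, and the one with the highest mean over all arrays stood for the gene. No genome build is given, so no coordinates are printed; the RefSeq table of GRCh38.p14 served for names and for which genes neighbour each other.

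The 12 arrays of each time point were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group, lmFit and eBayes, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts were RAD21 against control siRNA in vehicle and in estradiol, estradiol against vehicle under each siRNA, and the difference between those responses. Differences between 6 h and 3 h were tested as differences of differences over 24 arrays. A difference in intensity scale between the time points may enter these tests too. The response as a whole was measured as a slope through the origin over genes called at the other time point, with limma fry on the oriented difference. Arrays of 3 against 3 were also compared by an exact two-sided permutation test for RAD21.

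Tests of 19 gene lists used limma fry, adjusted over the lists of a contrast. They were cohesin and its regulators, classical estradiol-induced and estradiol-repressed genes, steroid receptors and their cofactors, DNA replication and G1/S, G2/M and mitosis, p53 targets, interferon-stimulated genes, immediate early genes, ribosome biogenesis, cholesterol biosynthesis, amino acid and ER stress, growth factor ligands and receptors, luminal epithelial markers, basal and mesenchymal markers, stromal and leukocyte markers, the protocadherin beta cluster, HOX genes and reference genes. Fry asks whether a list moves on balance one way and does not compare it with other genes. Camera, given below as the test with an estimated correlation, does compare a list with the other genes. A call lost there may stem from that comparison and not from correlation alone. Some genes belong to more than 1 list, such as EGR3, ESR1 and GATA3, and MCF7 cells express many of the luminal markers. All lists that passed had a median and a mean with the sign of their test.

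The lists, the contrasts given above, the alternatives and the rule for named genes were set before the data were examined, except for the fits of gene lists without 1 array. The estradiol response averaged over both time points and the tests of neighbouring genes and of RAD21 effects along the estradiol response were also added after results had been seen. The rule named RAD21, the 6 largest rises and the 6 largest falls among called genes whose arrays did not overlap between groups (3 each for estradiol in RAD21 siRNA, for RAD21 siRNA in estradiol and between times), up to 4 members of each list with the largest change whether or not they passed, and TFF1, GREB1, PGR, MYC, CCND1, ESR1, CXCL12 and PDZK1. PDZK1 had no probe set of its own and was left out. For the difference in response the same rule had no condition on overlap. Replicate numbers are shared between groups, the labels do not say that they pair samples, and the number was not in the model.

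Alternatives were an intensity trend with robust priors, the mean of all probe sets, leaving out the dimmest 40% of genes, centring arrays on their medians, quantile normalization, the replicate number as a block, all arrays in 1 fit, the other RAD21 probe sets, slopes over the classical lists or over 2-fold genes, camera with an estimated correlation for lists, and leaving out each array in turn. The fits were tested before use on simulated data with known changes and independent noise in each array. There, 2-fold changes were recovered for 94.0% to 100.0% of genes in contrasts of 2 groups, 1.41-fold changes for 28.4% to 52.2%, and a slope of 0.5 was found as 0.496. The SD of log2 differences between replicates of a group was 0.178 to 0.352. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.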

Results

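Gene expression was measured in MCF7 cells, an estrogen receptor positive breast cancer line. Hormone-depleted cells were transfected with siRNA against RAD21, a subunit of the cohesin ring that holds DNA loops and sister chromatids together, or with a control siRNA. After 48 h they received 100 nM estradiol or vehicle for 3 h or 6 h. The 2 siRNAs, 2 treatments and 2 time points made 8 groups of 3 arrays, from 3 independent experiments per time point. Each of the 24 arrays gave a log2 intensity for 49395 probe sets, from which 18132 genes were tested. Array medians lay between 5.45 and 5.50 at 3 h and between 4.51 and 4.61 at 6 h, so levels are compared within a time point and the number of arrays limits the precision. Changes are log2 differences ± the standard error of the limma fit, with 3 arrays in each group, and p-values are adjusted by the Benjamini-Hochberg method unless stated otherwise.

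RAD21 transcript was lower in every array that received RAD21 siRNA than in every array of control siRNA at the same time point. At 3 h it was at 17.9% of control in vehicle (log2 change −2.48 ± 0.32) and at 15.3% in estradiol (−2.71 ± 0.32). At 6 h it was at 13.9% in vehicle (−2.85 ± 0.22) and at 15.5% in estradiol (−2.69 ± 0.22). All 4 RAD21 probe sets fell, to between 11.2% and 25.6% of control. Replicate 3 kept more RAD21 transcript than the other RAD21 siRNA arrays at 3 h, with log2 intensities of 10.68 in vehicle and 10.56 in estradiol. The exact two-sided permutation p of each comparison was 0.1, the smallest that 3 against 3 arrays allow.

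**Figure D1:**
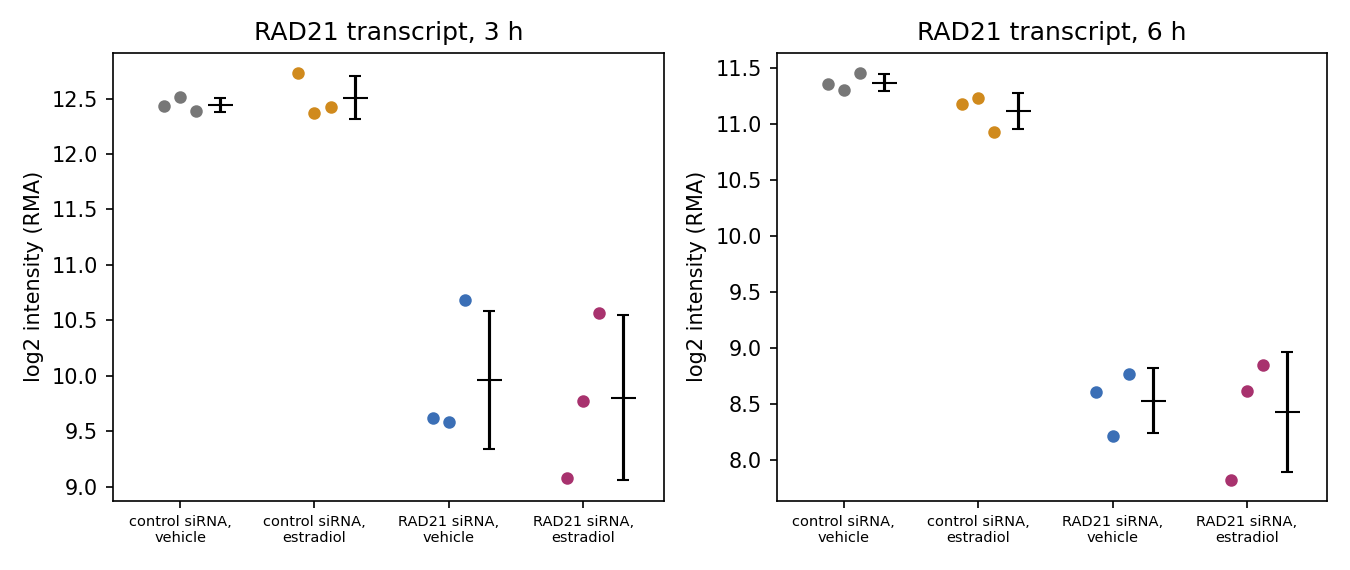
Log2 intensity of the RAD21 transcript in each array, by siRNA and treatment, at 3 h (left) and 6 h (right), with the mean and SD of the 3 arrays of a group as bars. All RAD21 siRNA arrays lie below all control siRNA arrays, and the third RAD21 siRNA replicate at 3 h lies highest among them, at 10.68 and 10.56.

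The first comparison asked what RAD21 siRNA changed in cells that had received no estradiol. The labels name a single RAD21 siRNA treatment, so loss of RAD21 and off-target effects of the siRNA cannot be told apart for any gene below. At 3 h of vehicle, the largest falls after RAD21 itself were in THBS1, the matrix glycoprotein thrombospondin (−2.09 ± 0.35), IL20, an interleukin (−2.08 ± 0.42), S1PR3, a receptor for sphingosine phosphate (−2.06 ± 0.20), AMIGO2, an adhesion protein (−2.05 ± 0.16), and SNRPA1, a spliceosome component (−1.86 ± 0.19). The largest rises were in VIM, the intermediate filament vimentin (1.60 ± 0.35), VWF, von Willebrand factor (1.54 ± 0.20), ANKRD22 (1.504 ± 0.25), PCDHB14 (1.48 ± 0.16), UTRN, the cytoskeletal protein utrophin (1.40 ± 0.18), and PCDHB10 (1.35 ± 0.23). At 6 h, UTRN (1.63 ± 0.18), VWF (1.63 ± 0.23), SAMD4A (1.60 ± 0.20), ANKRD22 (1.56 ± 0.28), IFIT1 (1.53 ± 0.34) and PCDHB14 (1.501 ± 0.18) rose most. THBS1 (−2.33 ± 0.29), the cyclin CCNG1 (−2.30 ± 0.19), IL20 (−2.04 ± 0.48), S1PR3 (−1.94 ± 0.22) and the matrix protein EFEMP1 (−1.91 ± 0.18) fell most after RAD21. IL20 read 3.18 to 4.06 in the RAD21 siRNA vehicle arrays at 6 h, below their medians, and signal over background was not analysed. Of the genes fixed for every comparison, the transcription factor MYC fell at both times (−0.91 ± 0.13 and −0.76 ± 0.13), while GREB1 (0.69 ± 0.16 and 0.54 ± 0.12) and the estrogen receptor gene ESR1 (0.56 ± 0.13 and 0.53 ± 0.12) rose. CXCL12, a chemokine, fell at 6 h (−1.05 ± 0.22) and stood at −0.84 ± 0.22 at 3 h, where it did not pass (adjusted p = 0.0616). At 3 h, VIM and IL20 no longer passed without control vehicle replicate 1 or 3 or RAD21 siRNA vehicle replicate 1 or 2 (adjusted p up to 0.108 and 0.0828). GREB1 and ESR1 each lost the call in 5 of the 6 fits without 1 array (up to 0.196 and 0.157). At 6 h, IL20 lost it in 5 of 6 (up to 0.103), ESR1 in 4 (0.102) and GREB1, IFIT1 and CXCL12 in 3 (0.111, 0.0911 and 0.0796), each of them without control vehicle replicate 1 among others.

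In all, limma called 480 genes at 3 h, 219 higher and 261 lower, and 675 genes at 6 h, 286 higher and 389 lower. The calls at the 2 times used different arrays, and 108 of the 219 higher and 177 of the 261 lower genes at 3 h were called in the same direction at 6 h, where 3.5 and 5.6 are the overlaps of independent lists. A test of the RAD21 effect at 6 h against that at 3 h called 0 genes in limma, with 654 at an unadjusted p under 0.05 and a smallest adjusted p of 0.646. Without control vehicle replicates 1, 2 or 3 at 3 h the count was 220, 251 or 259, and without RAD21 siRNA vehicle replicate 1 it was 247. Without control vehicle replicates 1, 2 or 3 at 6 h it was 264, 366 or 340. Without RAD21 siRNA vehicle replicate 2, which stood apart on the leading principal component, it was 385. Of the named genes called, 15 of 34 at 3 h and 23 of 47 at 6 h passed in every fit without 1 array.

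Protocadherin beta genes, a cluster of neuronal adhesion molecules, rose as a group. At 3 h, 10 of the 15 passed and 0 fell (adjusted p = 6.22e-05, fry), with 10 also adjusted over the list alone. At 6 h, 6 of 15 passed (adjusted p = 1.07e-07), and 10 adjusted over the list alone. PCDHB14 rose by 1.48 ± 0.16 and 1.501 ± 0.18, PCDHB13 by 1.17 ± 0.13 and 1.10 ± 0.20, and PCDHB16 by 1.05 ± 0.13 and 0.98 ± 0.14. The call held at both times in camera, which uses an estimated correlation and compares a list with the other genes (adjusted p = 0.00427 and 0.0042).

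Interferon-stimulated genes rose at 6 h, when 11 of 22 passed and 0 fell (adjusted p = 0.0114), and 11 passed adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.175). IFIT1 (1.53 ± 0.34), the ubiquitin-like modifier ISG15 (1.41 ± 0.20), IRF9, part of the interferon signalling complex (1.39 ± 0.30), and RIGI, a sensor of viral RNA (1.20 ± 0.17), changed most. At 3 h only IFIT1 passed in this list (1.11 ± 0.27), the list's adjusted p was 0.285, and no gene passed for a difference between the times. IFIT1 at 6 h lost its call without control vehicle replicate 1 or RAD21 siRNA vehicle replicate 1 or 2 (adjusted p up to 0.0911), and at 3 h in 5 of 6 such fits (0.187). IRF9 lost it without control vehicle replicate 1 or RAD21 siRNA vehicle replicate 1 (up to 0.0893).

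**Figure D2:**
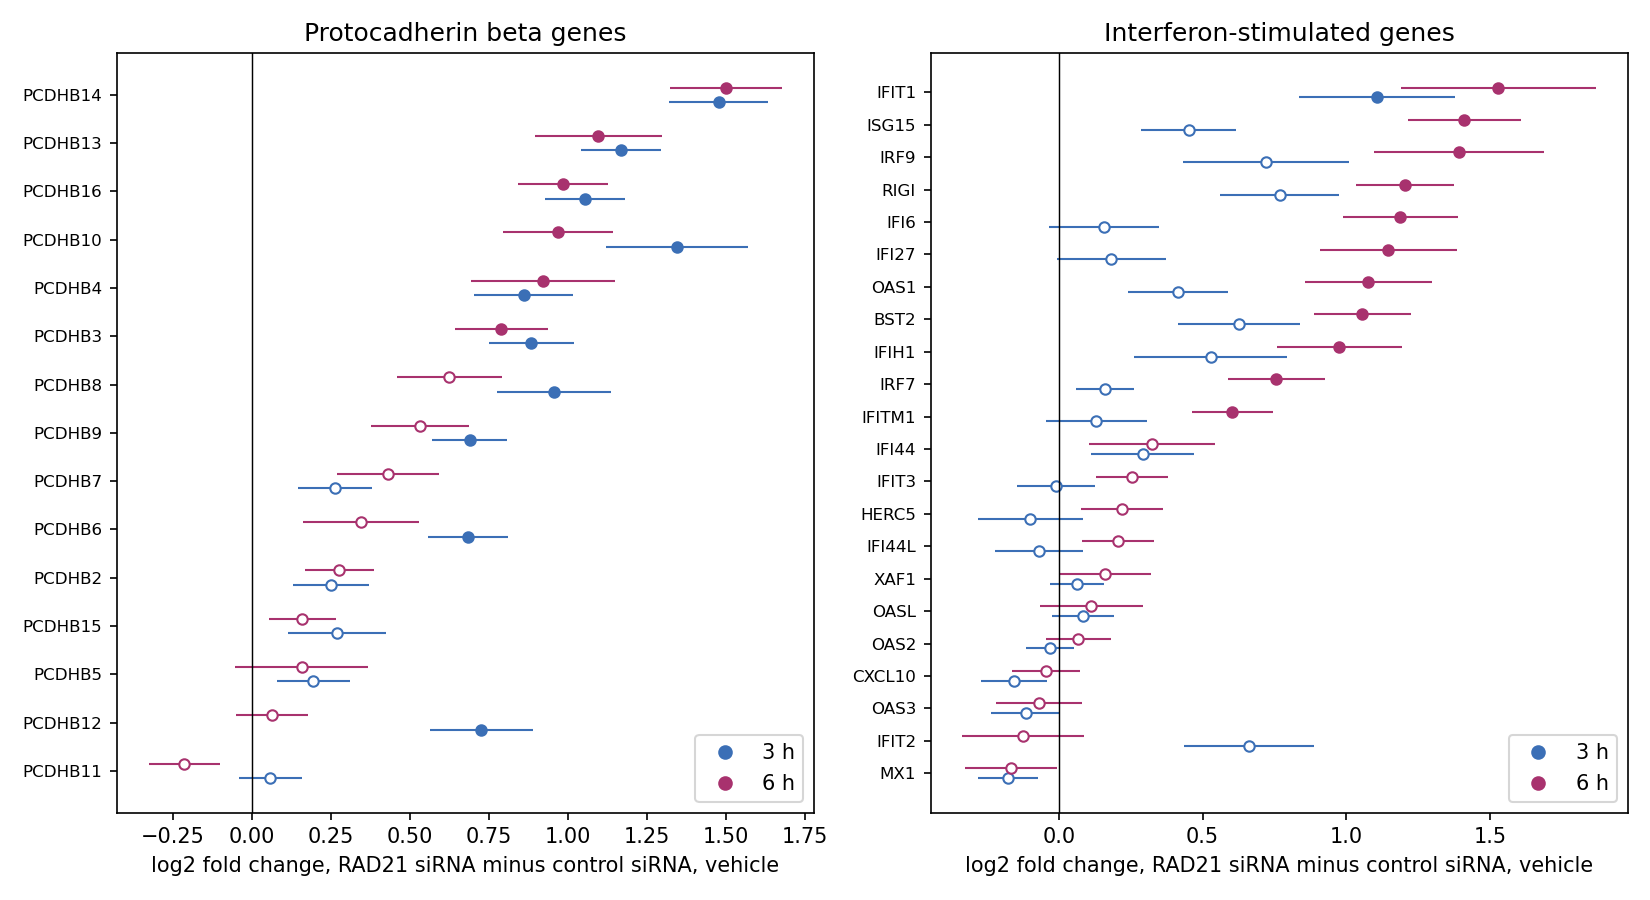
Log2 change between RAD21 siRNA and control siRNA in vehicle for the protocadherin beta genes (left) and the interferon-stimulated genes (right) at 3 h (blue) and 6 h (purple), with the standard error as bars and filled points at an adjusted p under 0.05. Of 15 protocadherin beta genes, 10 points are filled at 3 h and 6 at 6 h, and of 22 interferon-stimulated genes, 1 and 11.

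Genes of DNA replication and the G1/S transition fell on balance at both times (adjusted p = 0.0316 and 0.0125). With an estimated correlation the call was lost (adjusted p = 0.238 and 0.175), as it was at 3 h with the mean of all probe sets (0.0732). Of 38 measured, 3 fell at 3 h and 7 at 6 h (6 and 19 adjusted over the list alone) and 0 rose. CDC45, which unwinds DNA at the fork, fell at 3 h (−0.45 ± 0.09), and the helicase subunit MCM4 (−0.63 ± 0.13) and cyclin CCNE2 (−0.63 ± 0.15) fell at 6 h. Ribosome biogenesis genes fell likewise (adjusted p = 0.0316 and 0.0114), with 1 and 4 of 24 past the threshold (2 and 14 adjusted over the list alone), among them NOLC1 (−0.40 ± 0.09 and −0.54 ± 0.13). This list too had an adjusted p of 0.238 and 0.175 with an estimated correlation. At 3 h both lists also lost the call without control vehicle replicate 1 or 2 or RAD21 siRNA vehicle replicate 1 or 3 (0.0653, 0.12, 0.111 and 0.0963). CDC45 lost its call without control vehicle replicate 1 or 2 (adjusted p up to 0.0809), MCM4 without control vehicle replicate 1 or 2 or RAD21 siRNA vehicle replicate 3 (0.0525), and CCNE2 in 5 of 6 fits (0.113). NOLC1 lost it in 6 of 6 fits at 3 h (0.133) and 5 of 6 at 6 h (0.109). The 31 genes of G2/M and mitosis had 0 calls at either time (list adjusted p = 0.446 and 0.611).

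Cohesin genes other than RAD21 moved both ways. Of 20 measured, STAG1, a subunit that binds the ring, rose at both times (0.74 ± 0.15 and 0.65 ± 0.17), ESCO2, a cohesin acetyltransferase, fell at 3 h (−0.47 ± 0.09), and at 6 h the meiotic subunit REC8 rose (0.76 ± 0.17) and the core subunit SMC3 fell (−0.66 ± 0.14). The list's adjusted p was 0.993 and 0.616, and 3 rose and 1 fell at 3 h and 3 and 4 at 6 h adjusted over the list alone. The p53 targets were mixed too, with 3 higher and 1 lower of 22 at 3 h and 2 and 2 at 6 h (adjusted p = 0.128 and 0.192; 3 and 2 at both times adjusted over the list alone). Without control vehicle replicate 3 the list passed at 6 h (0.0415). CDKN1A, an inhibitor of cyclin-dependent kinases, rose (0.90 ± 0.20 and 0.99 ± 0.22), as did TP53I3 (0.72 ± 0.13 and 0.80 ± 0.12), and CCNG1 fell (−1.81 ± 0.18 and −2.30 ± 0.19). In fits without 1 array, 4 of 6 at 3 h and 3 of 6 at 6 h lost CDKN1A (adjusted p up to 0.114 and 0.111), and 4 and 5 of 6 lost STAG1 (up to 0.0707 and 0.164). ESCO2 lost its call in 3 of 6 (0.0842), REC8 in 5 (0.111), SMC3 without control vehicle replicate 1 or 3 (0.059) and TP53I3 at 3 h without control vehicle replicate 1 (0.0534).

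Genes known to be induced by estradiol rose on balance without estradiol (adjusted p = 0.0443 and 0.0206), but single members went both ways. The call was lost with an estimated correlation (adjusted p = 0.238 and 0.38) and with arrays centred on their medians (0.104 and 0.073). Of 37 measured, 8 rose and 2 fell at 3 h, and 7 rose and 3 fell at 6 h (11 and 4, then 9 and 4, adjusted over the list alone). SYTL5, a vesicle trafficking protein, rose (1.28 ± 0.11 and 1.29 ± 0.11), as did the cadherin CELSR2 (1.17 ± 0.24 and 1.11 ± 0.17), whereas AMIGO2 fell (−2.05 ± 0.16 and −1.80 ± 0.24). The list's call was also lost at 3 h without control vehicle replicate 1, 2 or 3 or RAD21 siRNA vehicle replicate 1 or 3 (0.0653, 0.156, 0.0829, 0.111 and 0.174) and at 6 h without control vehicle replicate 1 or 2 or RAD21 siRNA vehicle replicate 3 (0.06, 0.079 and 0.0522). CELSR2 did not pass at 3 h without control vehicle replicate 1 or 2 or RAD21 siRNA vehicle replicate 3 (adjusted p up to 0.0942).

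Luminal markers, HOX genes and markers of stromal cells and leukocytes passed at 6 h (adjusted p = 0.0206, 0.0206 and 0.0232), each on few members. With an estimated correlation, in camera, all 3 lost the call (adjusted p = 0.342, 0.254 and 0.254). The correlations were 0.032, −0.005 and 0.017, so correlation alone may not account for the loss. Of 18 luminal markers, ESR1 rose and the tight junction protein CLDN3 fell (−0.49 ± 0.12). Of 18 HOX genes 0 passed, and of 17 stromal and leukocyte markers VWF alone. All 3 also lost it with arrays centred on their medians (0.132, 0.0625 and 0.0701) and without control vehicle replicate 2 (0.0574 each) or RAD21 siRNA vehicle replicate 2 (0.084, 0.084 and 0.0983). The basal and mesenchymal markers did not pass as a list (adjusted p = 0.993 and 0.515), though VIM rose at both times and FN1, fibronectin (−0.63 ± 0.15), and the transcription factor SNAI1 (−0.51 ± 0.12) fell at 6 h. Without 1 array at 6 h, CLDN3 lost its call in 6 of 6 fits (adjusted p up to 0.114) and VIM, FN1 and SNAI1 in 4 each (0.094, 0.117 and 0.132). The stromal list was also lost without control vehicle replicate 1 (0.0643) or RAD21 siRNA vehicle replicate 3 (0.0569) and with the mean of all probe sets (0.215). Estradiol-repressed genes, steroid receptors and cofactors, immediate early genes, cholesterol biosynthesis, amino acid and ER stress genes, growth factor genes and reference genes gave adjusted p-values of 0.118, 0.807, 0.777, 0.501, 0.993, 0.813 and 0.501 at 3 h. At 6 h these were 0.0581, 0.692, 0.847, 0.515, 0.96, 0.616 and 0.413. At 6 h the repressed genes passed with the mean of all probe sets (0.0106) and without control vehicle replicate 3 (0.0201), and the reference genes with that mean (0.0219) and without RAD21 siRNA vehicle replicate 1 (0.0494). Among the reference genes YWHAZ fell at 6 h (−0.54 ± 0.10).

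The second comparison asked how control siRNA cells responded to estradiol. At 3 h the largest rises were in EGR3, an early growth response transcription factor (3.81 ± 0.27), RASGRP1, an activator of Ras (2.31 ± 0.14), IL20 (2.04 ± 0.42), LINC01588 (2.03 ± 0.25), ADRB1, an adrenergic receptor (2.03 ± 0.22), and the potassium channel KCNK5 (1.90 ± 0.21). ID2, an inhibitor of DNA binding by helix-loop-helix factors (−1.44 ± 0.26), AMIGO2 (−1.30 ± 0.16), NFKBIZ (−1.17 ± 0.12), FAM83B (−1.14 ± 0.23), CPEB2 (−1.12 ± 0.19) and TNFRSF11B, a decoy receptor (−1.11 ± 0.18), fell most. At 6 h EGR3 (4.20 ± 0.25), LINC01588 (3.14 ± 0.25), PDLIM3 (3.01 ± 0.14), FGFBP2 (2.78 ± 0.22), IL20 (2.62 ± 0.48) and MYBL1 (2.40 ± 0.16) rose most. The largest falls were in AMIGO2 (−2.16 ± 0.24), TP53INP1 (−1.82 ± 0.27), HMCN1 (−1.56 ± 0.27), S1PR3 (−1.55 ± 0.22), the interleukin receptor IL1R1 (−1.49 ± 0.24) and AHRR, a repressor of aryl hydrocarbon signalling (−1.45 ± 0.19). The progesterone receptor gene PGR rose by 1.58 ± 0.28 and 2.37 ± 0.26, GREB1 by 0.96 ± 0.16 and 1.501 ± 0.12, and MYC by 0.91 ± 0.13 and 0.70 ± 0.13. TFF1 (0.61 ± 0.11), the cyclin CCND1 (0.79 ± 0.19) and CXCL12 (1.58 ± 0.22) passed at 6 h and stood at 0.26 ± 0.09, 0.47 ± 0.16 and 0.93 ± 0.22 at 3 h, short of the threshold (adjusted p = 0.407, 0.346 and 0.0732). ESR1 did not pass at either time (−0.28 ± 0.13 and −0.41 ± 0.12, adjusted p = 0.712 and 0.109). At 3 h ID2 and PGR lost the call without control vehicle replicate 1 or control estradiol replicate 2 or 3 (adjusted p up to 0.0919 and 0.0789), CPEB2 without control estradiol replicate 2 (0.0526), and GREB1 without control estradiol replicate 3 (0.0663). FAM83B lost it in 5 of 6 fits (0.165). At 6 h TFF1 lost it without control estradiol replicate 3 (0.0535) and MYC without control vehicle replicate 2 (0.0531).

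Limma called 174 genes at 3 h, 125 higher and 49 lower, and 326 at 6 h, 201 higher and 125 lower. Of the 3 h calls, 89 of the 125 higher and 29 of the 49 lower were called in the same direction at 6 h, on other arrays, against 1.4 and 0.3 for independent lists. SYTL5 was the 1 gene whose response differed between the times (0.71 ± 0.11 at 3 h, 1.80 ± 0.11 at 6 h, difference 1.09 ± 0.15, adjusted p = 0.00595), and 0 passed when probe sets of a gene were averaged. Since the time points appear to have been normalized apart, a difference in intensity scale may be part of this difference. The 3 h count was 99 or 100 without control vehicle replicate 2 or 3 and 109 or 86 without control estradiol replicate 2 or 3. Lower genes then numbered 18, 22, 22 and 17, but 44 of 150 without control vehicle replicate 1. IL20 lost its 3 h call without any 1 of the 6 arrays (adjusted p up to 0.175). At 6 h the count was 204 or 194 without control vehicle replicate 2 or 3 and 168 or 181 without control estradiol replicate 2 or 3. Lower genes then numbered 73, 48, 38 and 47, but 138 of 282 without control estradiol replicate 1. CCND1 lost its call in 5 of 6 such fits (up to 0.193).

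Genes of the fixed list of classical estradiol-induced genes rose at both times (adjusted p = 2.25e-06 and 5.27e-07). Of 37, 11 rose at 3 h and 16 at 6 h (27 and 30 adjusted over the list alone), among them the receptor tyrosine kinase RET (1.62 ± 0.26 and 2.01 ± 0.22) and PGR, and 1 member, AMIGO2, fell. Of 17 classical repressed genes, 3 fell at 3 h and 6 at 6 h (8 and 14 adjusted over the list alone) and 0 rose (adjusted p = 0.00183 and 0.00026), such as CCNG2, an atypical cyclin (−0.88 ± 0.18 and −1.28 ± 0.19). Both lists held with an estimated correlation (adjusted p = 2.69e-05 and 5.2e-05 for the induced, 0.00679 and 0.00304 for the repressed genes). Steroid receptors and their cofactors fell on balance (adjusted p = 0.00566 and 0.00976), with GATA3 (−0.74 ± 0.09 and −0.77 ± 0.13) and TFAP2A (−0.71 ± 0.11 and −0.62 ± 0.13), transcription factors of the luminal lineage, lower at both times and TFAP2C higher at 3 h (0.55 ± 0.12), of 17 measured. With an estimated correlation this list passed at 3 h (adjusted p = 0.0433) and not at 6 h (0.122), and without control vehicle replicate 2 it did not pass at 3 h (0.0514). At 3 h CCNG2 and TFAP2C lost the call in 5 of 6 fits without 1 array (adjusted p up to 0.193 and 0.199), and at 6 h TFAP2A in 4 (0.135).

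At 6 h, ribosome biogenesis genes rose (2 of 24, 10 adjusted over the list alone), as did cholesterol biosynthesis genes (1 of 14, 7 adjusted over the list alone), both at an adjusted p of 0.0234. Both lost the call with an estimated correlation (adjusted p = 0.186 and 0.137). POLR1C, a shared polymerase subunit (0.46 ± 0.10), WDR12 (0.45 ± 0.10) and the sterol enzyme MSMO1 (0.81 ± 0.15) passed. Protocadherin beta genes and basal markers shifted down with 0 members past the threshold (adjusted p = 0.00045 and 0.0441). Both lost the call with an estimated correlation (adjusted p = 0.122 and 0.217), and the basal markers with the mean of all probe sets (0.146). Without control vehicle replicate 2 or 3 or control estradiol replicate 2 the ribosome list stood at 0.0742, 0.0745 and 0.0678 and the cholesterol list at 0.0597, 0.0745 and 0.0693. The basal list was lost without control vehicle replicate 2 or 3 (0.152 and 0.114) or control estradiol replicate 1 or 3 (0.107 and 0.113). The ribosome list was also lost without control estradiol replicate 1 (0.0728) and the cholesterol list without control estradiol replicate 3 (0.0684). MSMO1 lost its call without control estradiol replicate 2 or 3 (up to 0.0622). POLR1C and KLF4 lost it in 5 of 6 fits (0.173 and 0.138), WDR12 in 6 (0.135) and IRS2 at 3 h in 3 (0.0644). Of the immediate early genes, EGR3, the AP-1 subunit FOS (1.89 ± 0.26) and KLF4 (0.92 ± 0.18) rose at 3 h and EGR3 at 6 h, and the list of 16 did not pass (adjusted p = 0.21 and 0.0679), though it did without control vehicle replicate 1 (0.0391 and 0.0453). Of 32 growth factor genes, IRS2, an insulin receptor substrate (1.21 ± 0.21 and 1.51 ± 0.24), and the binding protein IGFBP4 (1.14 ± 0.18 and 1.76 ± 0.13) rose at both times, and the list did not pass (0.226 and 0.451). The remaining lists, from cohesin genes to reference genes, had an adjusted p of 0.0679 or more at both times. Without control vehicle replicate 1, however, p53 targets passed at both times (0.0391 and 0.00172) and luminal markers at 6 h (0.00433), and p53 targets passed at 6 h with the mean of all probe sets (0.0469).

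The third comparison gave the same treatment to cells with RAD21 siRNA. Estradiol raised SMTNL2 (2.92 ± 0.20), ADRB1 (2.70 ± 0.22) and EGR3 (2.44 ± 0.27) most at 3 h and lowered the DNA-binding inhibitors ID1 (−2.14 ± 0.47) and ID2 (−1.90 ± 0.26) and the exchange factor VAV3 (−1.73 ± 0.30). At 6 h PDLIM3 (3.40 ± 0.14), LINC01588 (3.39 ± 0.25) and FGFBP2 (3.32 ± 0.22) rose most, and TM4SF1 (−1.90 ± 0.20), AMIGO2 (−1.70 ± 0.24) and DDIT4, an inhibitor of growth signalling (−1.67 ± 0.20), fell most. PGR rose by 1.33 ± 0.28 and 2.16 ± 0.26 and MYC by 0.97 ± 0.13 and 0.78 ± 0.13. GREB1 rose at 6 h (1.62 ± 0.12) and stood at 0.66 ± 0.16 at 3 h (adjusted p = 0.0663), and CXCL12 (1.63 ± 0.22) rose and ESR1 (−0.67 ± 0.12) fell at 6 h. ID1 and PGR lost their 3 h calls without RAD21 siRNA vehicle replicate 1 or 2 or RAD21 siRNA estradiol replicate 2 or 3 (adjusted p up to 0.157 and 0.131). Of the classical induced genes, 14 of 37 rose at 3 h and 22 at 6 h (24 and 28 adjusted over the list alone), with the ubiquitin ligase SIAH2 (1.46 ± 0.09 at 3 h) and RET (1.65 ± 0.26 and 1.95 ± 0.22) among them, and AMIGO2 fell at both times. Of the repressed genes 5 and 12 of 17 fell (11 and 12 adjusted over the list alone) and 0 rose, including SMAD6, an inhibitor of BMP signalling (−1.52 ± 0.27 and −1.56 ± 0.29). Both lists passed at both times with fry (adjusted p = 2.98e-06 and 5.24e-07, then 0.000379 and 0.000157) and with an estimated correlation (0.000123 and 0.000131, then 0.00256 and 0.0115).

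The receptor and cofactor list fell in these cells too (adjusted p = 0.000671 at 3 h and 0.00854 at 6 h), with GATA3 at −1.15 ± 0.09 and −0.81 ± 0.13. With an estimated correlation it passed at 3 h (adjusted p = 0.0118) and not at 6 h (0.293), where it also missed with arrays centred on their medians (0.0705). At 6 h ribosome biogenesis (6 of 24, adjusted p = 0.00854) and cholesterol biosynthesis genes (4 of 14, adjusted p = 0.0148) rose, with 13 and 7 adjusted over the list alone. Both lost the call with an estimated correlation (adjusted p = 0.26 each). Among them were RRS1 (0.57 ± 0.12) and WDR12 (0.51 ± 0.10), and the sterol genes HMGCS1 (0.92 ± 0.19), MSMO1 (0.84 ± 0.15) and INSIG1 (0.65 ± 0.12). Luminal markers fell (4 of 18, 1 higher and 7 lower adjusted over the list alone; adjusted p = 0.00509), with SPDEF (−0.90 ± 0.16) and CLDN4 (−0.61 ± 0.11) beside GATA3 and ESR1. This list had an adjusted p of 0.299 with an estimated correlation. Some lists that did not pass with all arrays passed without 1 array. At 3 h these were ribosome biogenesis without RAD21 siRNA vehicle replicate 2 (0.00137, 0.134 with all arrays) and cholesterol biosynthesis without RAD21 siRNA estradiol replicate 1 (0.00399, 0.191 with all). At 6 h they were immediate early and amino acid and ER stress genes without RAD21 siRNA vehicle replicate 1 (0.041 and 0.0211, 0.199 and 0.223 with all) and HOX genes without RAD21 siRNA estradiol replicate 1 (0.00978, 0.0707 with all). Limma called 302 genes at 3 h, 206 higher and 96 lower, and 972 at 6 h, 573 higher and 399 lower, or 745 and 291 of 1036 with arrays centred on their medians. RRS1 lost its call without RAD21 siRNA estradiol replicate 3 (adjusted p = 0.081). The count was 195 at 3 h without RAD21 siRNA estradiol replicate 2. At 6 h it was 551 without RAD21 siRNA vehicle replicate 2, and 591 or 427 without RAD21 siRNA estradiol replicate 2 or 3. Limma called 0 genes for a different response at 6 h than at 3 h (1543 at an unadjusted p under 0.05, PDLIM3 closest at adjusted p = 0.0642), and between 0 and 2 in the other fits of all arrays. The count became 1 without RAD21 siRNA vehicle replicate 3 or RAD21 siRNA estradiol replicate 1 at 3 h, and 2 or 3 without RAD21 siRNA vehicle replicate 1 or 3 at 6 h.

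The fourth comparison asked whether RAD21 siRNA changed the estradiol response itself. EGR3 rose by 3.81 ± 0.27 in control siRNA cells and by 2.44 ± 0.27 in RAD21 siRNA cells at 3 h, and by 4.20 ± 0.25 and 3.17 ± 0.25 at 6 h. The differences of −1.37 ± 0.39 and −1.03 ± 0.35 did not pass (adjusted p = 1 and 0.749, unadjusted 0.00332 and 0.0107). IL20, whose difference was singled out after its values were seen, rose by 2.04 ± 0.42 and 2.62 ± 0.48 in control siRNA cells and stood at 0.85 ± 0.42 and 1.57 ± 0.48 in RAD21 siRNA cells. Its differences of −1.19 ± 0.60 and −1.05 ± 0.68 did not pass either (unadjusted p = 0.0678 and 0.143). IL20 lay below the array median in every RAD21 siRNA vehicle array, so its response in these cells starts from dim values. EGR3 lay below the array median in every control siRNA vehicle array, so its response in control siRNA cells starts from dim values too. Of the genes called in control siRNA cells, 94 of 125 higher and 33 of 49 lower at 3 h, and 153 of 201 and 82 of 125 at 6 h, were called in the same direction in RAD21 siRNA cells, with 0 called in the opposite one. Independent lists would share 1.4, 0.3, 6.4 and 2.8.

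**Figure D3:**
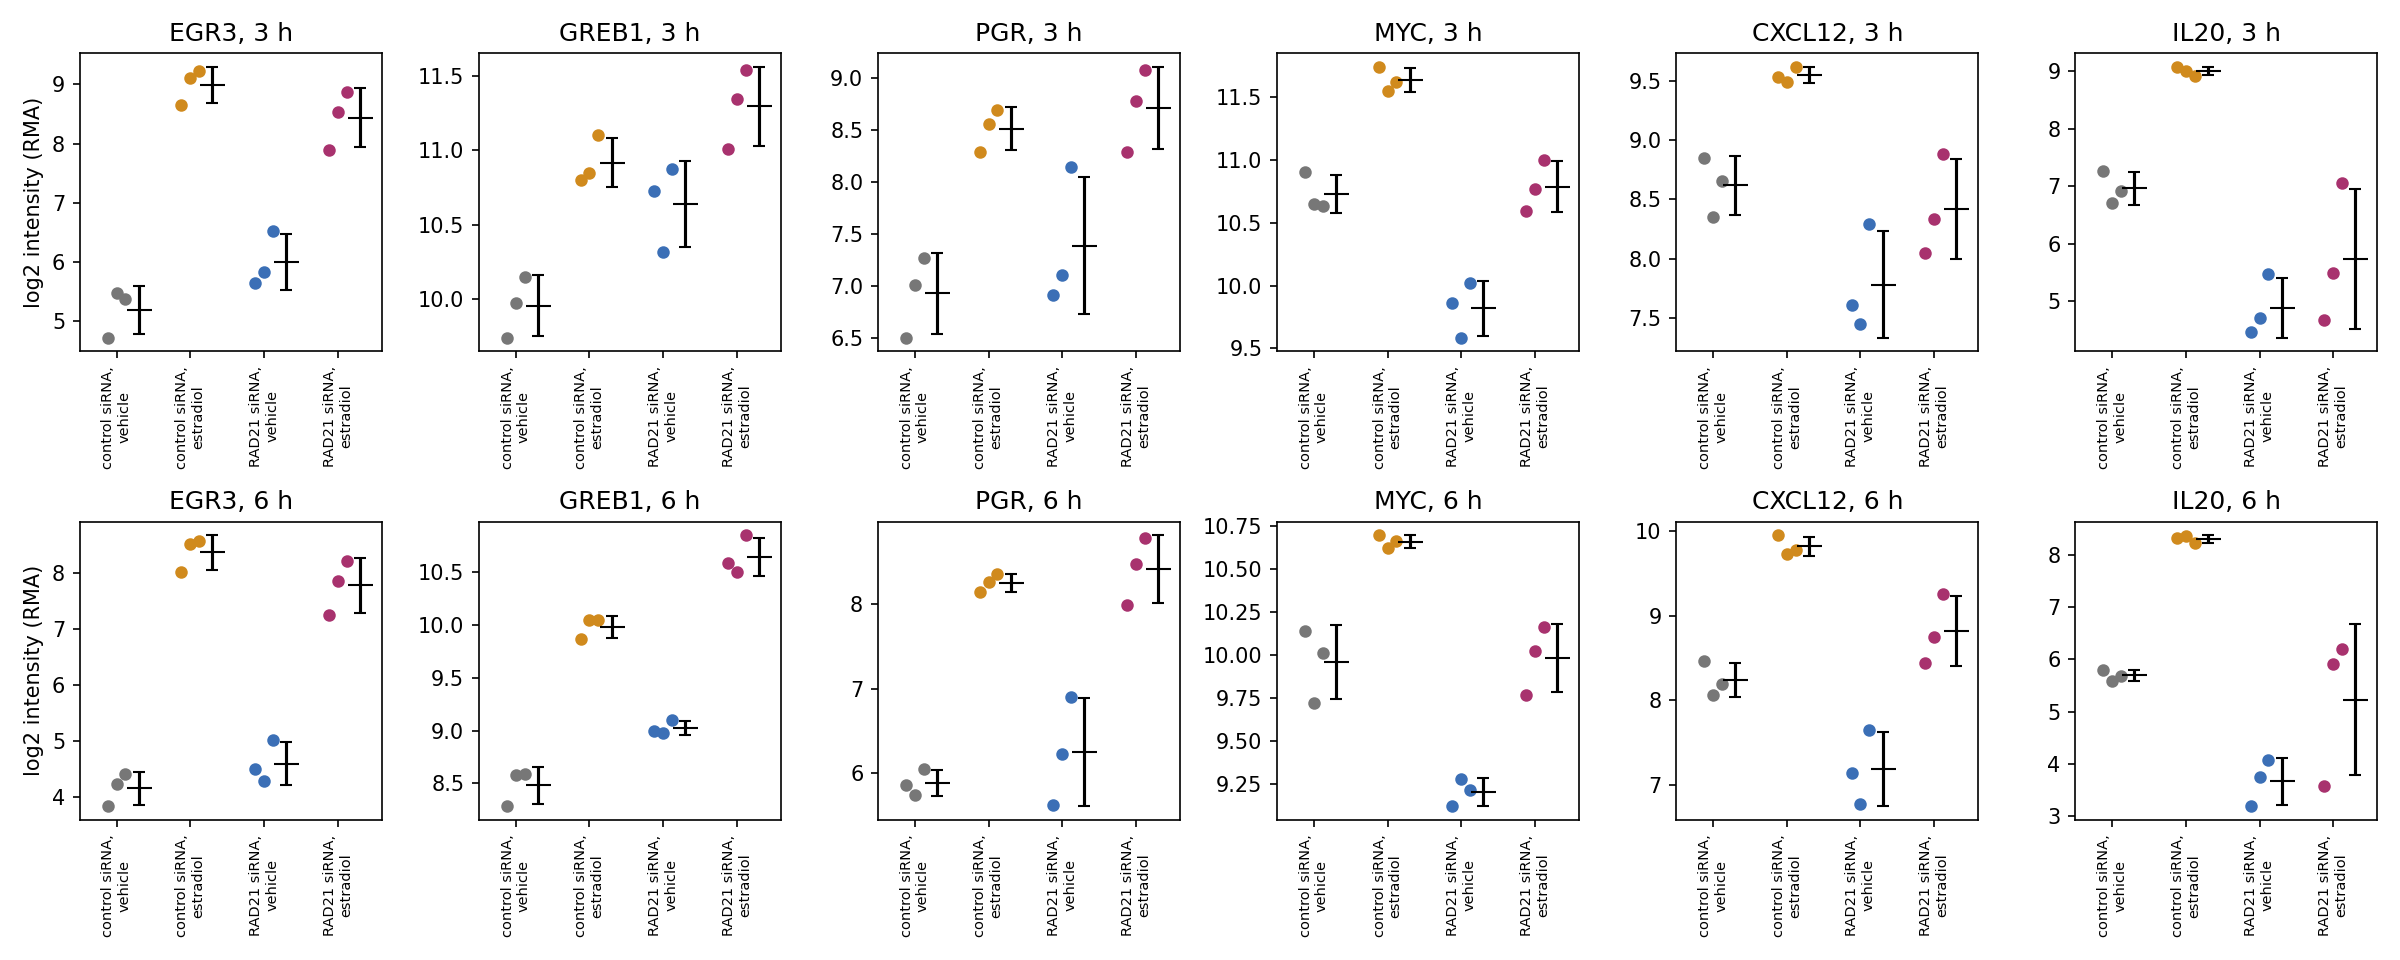
Log2 intensity of EGR3, GREB1, PGR, MYC, CXCL12 and IL20 in each array at 3 h (top) and 6 h (bottom), by siRNA and treatment, with the mean and SD of the 3 arrays of a group as bars. EGR3 rises with estradiol under both siRNAs, by 3.81 and 2.44 at 3 h, and MYC lies lower with RAD21 siRNA in both treatments.

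Limma called 0 genes for a different estradiol response at 3 h, with 453 at an unadjusted p under 0.05 where 907 are expected by chance. At 6 h it also called 0, with 1185 at an unadjusted p under 0.05 and CASTOR1 closest (adjusted p = 0.111). With an intensity trend and robust priors the count at 6 h was 2, and in a fit of all arrays 1. With the replicate number as a block, the count at 3 h was 1 (adjusted p = 0.0399 in limma), with 675 at an unadjusted p under 0.05. Both 453 and 675 lie below the chance number, so the test at 3 h may be too strict. Variation shared by same-numbered arrays, which the main fit leaves in the spread, may be part of this. The 0 calls at 3 h therefore do not show equal responses. Of the 19 gene lists 0 passed at either time, the lowest adjusted p being 0.0862 for protocadherin beta genes at 6 h. Without control vehicle replicate 1 or RAD21 siRNA estradiol replicate 3 at 6 h, that list passed (0.028 and 0.0475). On simulated data of this design, a 2-fold difference in response was recovered for 91.0% of genes at 3 h and 76.1% at 6 h, and a 1.41-fold difference for 4.5% and 7.5%. The simulation drew independent noise for each array and changed 200 genes at once, so recovery on the real arrays may be lower. The estimated difference for EGR3 was over 2-fold at both times and did not pass, so 0 calls do not exclude such differences.

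To measure the response as a whole, genes were chosen at one time point and measured at the other. Over the 326 genes called at 6 h in control siRNA cells, the slope of the 3 h response in RAD21 siRNA cells on that in control siRNA cells was 0.947 and the median difference along the response 0.03 (fry p = 0.626, n = 326 genes). For the 174 genes called at 3 h, the slope at 6 h was 0.965 and the median difference −0.002 (fry p = 0.719, n = 174 genes). For a difference in either direction, the mixed fry p of the 326 genes was 0.214 at 3 h (n = 326 genes) and that of the 174 genes 0.00746 at 6 h (n = 174 genes). The latter was 0.0521, 0.0581 and 0.0555 without control vehicle replicate 3, control estradiol replicate 2 or RAD21 siRNA estradiol replicate 1. With the replicate number as a block, the mixed fry p was 0.0178 at 3 h and 9.58e-06 at 6 h. Without any 1 array these slopes over all chosen genes stayed between 0.918 and 0.977 at 3 h and between 0.946 and 0.993 at 6 h. With all arrays, genes raised and lowered by estradiol had slopes of 0.926 and 1.03 at 3 h and of 0.982 and 0.87 at 6 h. At 6 h the median difference was 0.013 for the 125 raised genes and −0.112 for the 49 lowered ones. Raised and lowered genes were not tested apart. Noise in the control siRNA response pulls such a slope below 1 even when responses are equal, so these values do not show a smaller response.

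**Figure D4:**
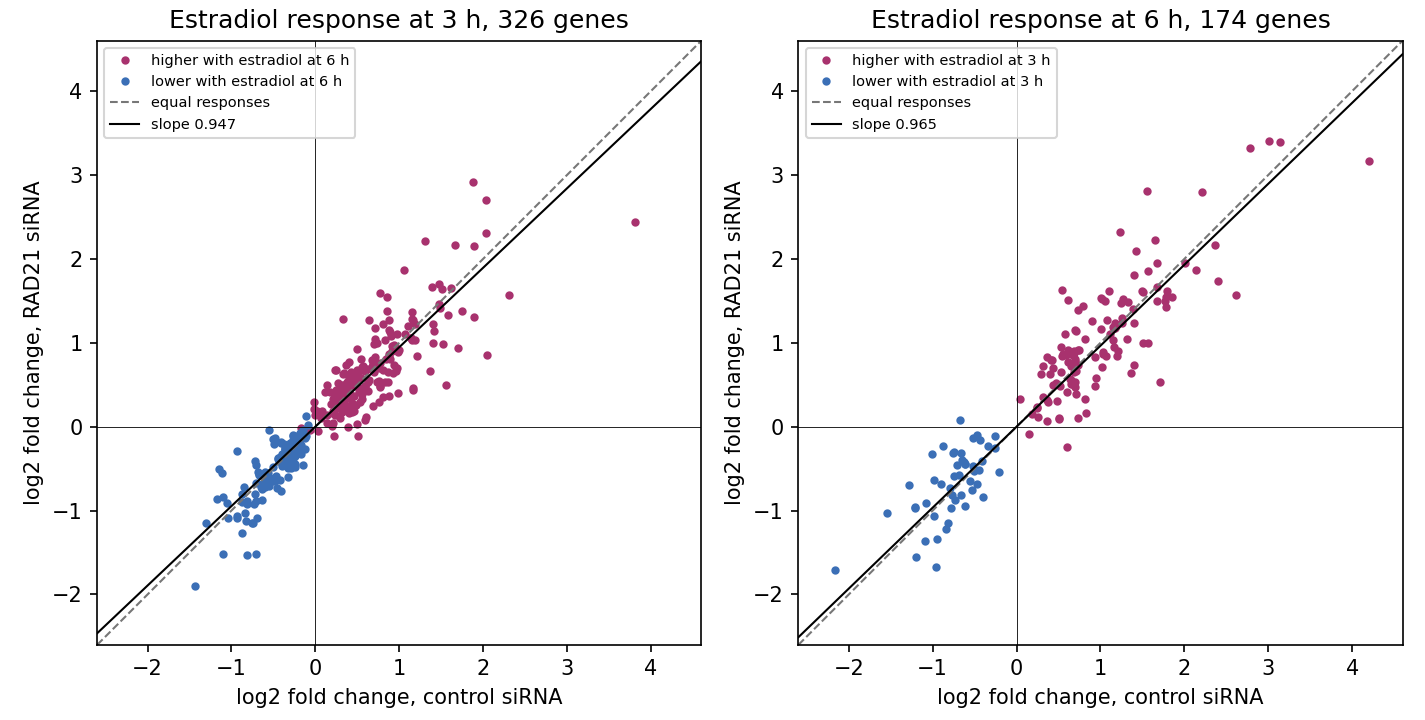
Log2 response to estradiol in RAD21 siRNA cells (y axis) against that in control siRNA cells (x axis), one point per gene, at 3 h for 326 genes called at 6 h (left) and at 6 h for 174 genes called at 3 h (right). The solid lines through the origin have slopes of 0.947 and 0.965, and the dashed lines mark equal responses.

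The fifth comparison was between the siRNAs in the presence of estradiol. IL20 (−3.27 ± 0.42 and −3.09 ± 0.48) and THBS1 (−2.27 ± 0.35 and −1.91 ± 0.29) fell most beside RAD21 at both times. IL20 read 3.56 in RAD21 siRNA estradiol replicate 1 at 6 h, below that array's median of 4.53, and signal over background was not analysed. SYNPO2L (1.80 ± 0.20), FGFBP2 (1.64 ± 0.17) and VIM (1.59 ± 0.35) rose most at 3 h, and VWF (1.97 ± 0.23), PGLYRP2 (1.71 ± 0.33) and LINC01588 (1.71 ± 0.25) at 6 h. MYC fell (−0.85 ± 0.13 and −0.68 ± 0.13), as did CXCL12 (−1.12 ± 0.22 and −1.005 ± 0.22), and GREB1 rose at 6 h (0.66 ± 0.12) and ESR1 at 3 h (0.60 ± 0.13). Protocadherin beta genes rose again, 8 of 15 at 3 h and 6 at 6 h (12 and 11 adjusted over the list alone), with adjusted p of 0.000116 and 2.21e-08 (0.0137 and 0.000393 with an estimated correlation). PCDHB14 rose by 1.42 ± 0.16 and 1.51 ± 0.18. Of the growth factor genes, 3 rose and 4 fell at 3 h and 1 rose and 3 fell at 6 h, with the insulin receptor substrates IRS1 (−1.22 ± 0.19 and −0.77 ± 0.17) and IRS2 (−1.14 ± 0.21 and −1.19 ± 0.24) lower at both times and the list not past the threshold (adjusted p = 0.318 and 0.74). Of the interferon-stimulated genes, 4 of 22 rose at 6 h, among them IFIT1 (1.42 ± 0.34) and RIGI (0.90 ± 0.17), and 0 at 3 h (adjusted p = 0.0535 and 0.318). Adjusted over the list alone, 10 rose at 6 h and 0 at 3 h. At 6 h that list passed with arrays centred on their medians (0.0427) and without RAD21 siRNA estradiol replicate 2 (0.0346), as did HOX genes without that array (0.0355) and p53 targets with the mean of all probe sets (0.0481). At 3 h the induced, DNA replication and ribosome lists did not pass (0.0933, 0.087 and 0.087). The induced and ribosome lists did with the mean of all probe sets (0.0184 and 0.0499), and the DNA replication and ribosome lists with arrays centred (0.0174 and 0.00826). At 6 h the induced genes (7 higher, 3 lower, adjusted p = 0.033) passed upward, and DNA replication (0 members, 0.0337) and ribosome biogenesis genes (1 member, RRP9, 0.033) downward. Adjusted over the list alone, 10 induced genes rose and 4 fell, and 9 DNA replication and 2 ribosome biogenesis genes fell. With an estimated correlation these 3 lists had an adjusted p of 0.223 each, and without RAD21 siRNA estradiol replicate 1 of 0.12 each, and DNA replication had 0.0514 with arrays centred on their medians. Without RAD21 siRNA estradiol replicate 3 they had 0.117, 0.117 and 0.0945, and they were also lost without some control estradiol arrays (0.0848 to 0.1). At 3 h VIM, ESR1 and CXCL12 lost the call in 3 of 6 fits each, among them those without RAD21 siRNA estradiol replicate 1 (adjusted p up to 0.107, 0.0986 and 0.0593). At 6 h MYC lost it without that replicate (0.0766), IRS2 without any 1 control estradiol array (0.0849). PGLYRP2 and RIGI lost it in 3 fits (0.0645 and 0.0831), IFIT1 in 5 (0.198) and RRP9 in 6 (0.159).

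Limma called 584 genes at 3 h, 309 higher and 275 lower, or 244 and 342 of 586 with arrays centred on their medians, and 440 at 6 h, 240 higher and 200 lower. Of the genes called in vehicle, 147 of 219 higher and 179 of 261 lower at 3 h, and 113 of 286 and 118 of 389 at 6 h, were called in the same direction in estradiol, and 0 in the opposite one. Independent lists would share 3.7, 4.0, 3.8 and 4.3. At 3 h the count was 259, 302 or 327 without control estradiol replicate 1, 2 or 3 and 281 or 268 without RAD21 siRNA estradiol replicate 1 or 2. At 6 h it was 238, 178 or 229 without control estradiol replicate 1, 2 or 3 and 131, 281 or 275 without RAD21 siRNA estradiol replicate 1, 2 or 3. CXCL12 at 6 h lost its call in 5 of 6 fits without 1 array (adjusted p up to 0.146) and IRS1 in 5 (up to 0.159).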

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

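The test of the estradiol response averaged over both time points, which gave KIF21A, CASTOR1 and USP31, the fits of a gene list without 1 array, and the bound of 423 genes for estradiol at 6 h were chosen after the results were seen. SYTL5 drew attention because its estradiol response in control siRNA cells differed between the times (0.71 at 3 h, 1.80 at 6 h, difference 1.09 ± 0.15, adjusted p = 0.00595 in limma); in RAD21 siRNA cells its responses were 0.83 and 1.62. KIF21A, a kinesin, responded more to estradiol in RAD21 siRNA cells when both time points were averaged (difference 0.71 ± 0.09, adjusted p = 0.00103), with 0.27 and 0.82 at 3 h and 0.29 and 1.17 at 6 h in control and RAD21 siRNA cells. CASTOR1, an arginine sensor, differed by 1.09 ± 0.17 (adjusted p = 0.0127), with 0.40 and 1.27 at 3 h and 0.19 and 1.51 at 6 h. USP31 differed by 0.80 ± 0.13 (adjusted p = 0.0127), with 0.85 and 1.54 at 3 h and 0.61 and 1.52 at 6 h.

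Interferon-stimulated genes were higher after RAD21 siRNA in vehicle at 6 h, 11 of 22 past the threshold. Against a single outlying array, the list's lowest median change in the 6 fits without 1 array was 0.419, beside 0.463 with all arrays, though the members past the threshold fell to 4 without control vehicle replicate 1 or RAD21 siRNA vehicle replicate 1. A response to the RNA duplex may also raise such genes, and since control siRNA cells were transfected too, this leaves one particular to the RAD21 duplex. Of 9 measured interferon and NF-kB target genes, 0 passed in limma (median 0.125, highest CXCL8 at 0.96, adjusted p = 0.321). That duplex and the loss of RAD21 came together in every RAD21 siRNA array, so these cannot be told apart, and loss of RAD21 stays open as the biological explanation.

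Protocadherin beta genes were higher after RAD21 siRNA at both times. Cross-hybridization between these near-identical genes needs the rise to lie in probe sets marked as shared; the 23 unmarked ones had medians of 0.54 at 3 h and 0.431 at 6 h, and 22 of them were higher at each time, against medians of 0.559 and 0.352 for 6 marked ones. The mark covers only the platform's own prediction. A single outlying array is argued against by the lowest list median without 1 array, 0.45. Since both technical explanations tested were argued against, a candidate explanation is that RAD21 loss raises the cluster, as a hypothesis found and tested on the same arrays; an off-target effect of the siRNA was not tested.

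Estradiol changed 972 genes in RAD21 siRNA cells and 326 in control siRNA cells at 6 h, whereas limma called 0 genes for a difference in response (1185 at an unadjusted p under 0.05). Without RAD21 siRNA estradiol replicate 3 the count was 427, below 489, 1.5 times the control count with all arrays, and above 423, 1.5 times the highest control count without 1 control array (282, lowest 168), so it stays open whether a single array accounts for the gap. Without RAD21 siRNA vehicle replicate 2 it was 551, without RAD21 siRNA estradiol replicate 2 it was 591, and without the other 3 arrays it was 665, 690 and 1071. Equal responses that crossed the threshold in one arm by chance are also consistent with the data: over 737 genes called in RAD21 siRNA cells alone, the 3 h responses had medians of 0.209 in RAD21 and 0.185 in control siRNA cells and gave a fry p of 0.5 for a difference, although 447 were larger in RAD21 siRNA cells, with a median difference of 0.041. A true difference in response at 6 h, where these medians were 0.584 and 0.273 on the arrays that chose the genes, stays open.

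Each contrast of 3 against 3 arrays has 10 splits, too few for a share under 0.05, and the real split alone, 1 of 10, gave as many genes. Real counts and the highest of the other splits at 3 h were 480 and 0 for RAD21 siRNA in vehicle, 174 and 0 for estradiol in control siRNA, 302 and 33 for estradiol in RAD21 siRNA, and 584 and 0 for RAD21 siRNA in estradiol. At 6 h they were 675 and 0, 326 and 0, 972 and 1, and 440 and 0. Every other split mixes arrays of both groups, so a true difference between the groups also lowers its count. These low counts therefore do not measure chance. For the difference in estradiol response the real count was 0, which 100 of 100 reassignments of residuals reach whatever the data, so this says nothing about chance (highest counts 453 at 3 h and 14 at 6 h). It says nothing either between the times for estradiol in RAD21 siRNA (0 real, 100 of 100, highest 342) and for RAD21 siRNA in vehicle (0 real, 100 of 100, highest 108). For SYTL5's contrast 2 of 100 gave at least 1 gene (highest 12), and for the averaged response 2 of 100 gave at least 3 (highest 139), a share under 0.05 if residuals can be exchanged freely between arrays. The reassignments that called 453, 342, 139 and 108 genes point to a structure of the samples beyond their groups, so these shares do not exclude chance by themselves.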

How the results depend on the processing

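The fits of gene lists without 1 array were chosen after seeing the data; all other alternatives were set before. RAD21 fell under every alternative run. The slopes of the estradiol response, over raised and lowered genes together, stayed under 1. Noise in the control siRNA response alone pulls such a slope down, so their side decides nothing. With the replicate block, counts at 3 h were 874 (RAD21 siRNA in vehicle), 327 and 499 (estradiol in control and RAD21 siRNA), 1035 (RAD21 siRNA in estradiol) and 1 (difference in response), and at 6 h 1025, 529 and 669 (estradiol in RAD21 siRNA stayed within 1.5 times), with 1 for estradiol in RAD21 siRNA between times. The block gave 5, 5 and 4 lists at 3 h for estradiol in control and RAD21 siRNA and for RAD21 siRNA in estradiol, against 3, 3 and 1, and stromal markers lost their call (0.0534). Among lists that passed with it were immediate early genes (0.000242 and 0.00272) and amino acid and ER stress genes (0.0233 and 0.0413) for estradiol in control siRNA at 3 h and 6 h. It gave 6 genes for the response averaged over both times, against 3, and moved no other count of calls by over 1.5 times. For a difference of the estradiol response in either direction, its mixed fry p was 0.0178 at 3 h (n = 326 genes, 0.214 without the block) and 9.58e-06 at 6 h (n = 174 genes). In the check of pairing, same-numbered arrays correlated at −0.061 to 0.522 at 3 h (16 of 18 pairs over 0.1, 10 of 12 arrays best with their own number) and −0.027 to 0.337 at 6 h (13 of 18, 12 of 12). Their median correlations were 0.237 and 0.18, against −0.146 and −0.093 for arrays of other numbers. The labels give 3 independent experiments per time point but do not say that the numbers mark them. These values point to shared experiments, which the main fits leave out. An intensity trend with robust priors gave 1035 and 675 genes for RAD21 siRNA in vehicle and in estradiol at 6 h, 2 for the difference in response at 6 h, and 2 for estradiol in RAD21 siRNA between times. All arrays in 1 fit gave 1019, 520, 736 and 1 at 6 h for RAD21 siRNA in vehicle, estradiol in control siRNA, RAD21 siRNA in estradiol and the difference. For estradiol between times, the mean of all probe sets gave 0 in control and 1 in RAD21 siRNA, centring 2 and quantile normalization 1 in RAD21 siRNA. Camera gave 1 list for RAD21 siRNA in vehicle at 3 h (main 4) and 1 at 6 h (8), 2 for estradiol at 6 h in each cell (7 and 6), and 1 for RAD21 siRNA in estradiol at 6 h (4). For RAD21 siRNA in estradiol at 3 h, mean probe sets and centring gave 3 lists each, and for RAD21 siRNA in vehicle at 6 h centring gave 4. The cause was not tested for any of these; more residual freedom is part of a fit of all arrays.

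Without 1 array, counts were 220 to 480, 86 to 150, 195 to 293 and 259 to 604 at 3 h (RAD21 siRNA in vehicle, estradiol in control and RAD21 siRNA, RAD21 siRNA in estradiol), 264 to 533, 168 to 282, 427 to 1071 and 131 to 281 at 6 h, 0 for the difference in response at either time, 1 and 0 to 3 for estradiol between times in control and RAD21 siRNA, and 0 for RAD21 siRNA between times. Lists numbered 1 to 4, 2 to 5, 3 to 4 and 1 at 3 h, 4 to 10, 4 to 10, 6 to 8 and 1 to 6 at 6 h, and 0 to 1 for the difference at 6 h. Of list calls, 49 were lost and 17 gained over the fits without 1 array, 32 lost and 9 gained under other alternatives, and 1 lost and 12 gained with the block. Of calls of named genes, 459 were lost and 7 gained over all fits without 1 array, 99 were lost and 12 gained under other alternatives, and 2 lost and 6 gained with the block. Fits of 2 arrays in a group take the spread from all groups. No signal over background was analysed here, so dim genes were judged only by leaving out the lowest 40%.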

Other observations

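The test of RAD21 siRNA effects along the estradiol response, the test of neighbouring genes, and the test of the estradiol response averaged over both time points were chosen after results had been seen. Some genes changed by RAD21 siRNA were neighbours. MLF1, GFM1 and LXN, a run of adjacent genes, were lower at both times in vehicle, as were the pairs DR1 and FNBP1L, TMTC3 and KITLG, UNG and ACACB, CDKN3 and CNIH1, TTC7B and RPS6KA5, and CAPN7 and SH3BP5, while B4GALT1 and SPINK4 were higher. These pairs were named after their values were seen. At 6 h the cohesin genes STAG1 and REC8 were higher beside PCCB and IRF9, and SMC3 was lower beside DUSP5.

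A hypothesis from this is that RAD21 loss may act on neighbouring genes together. Over 16377 pairs of neighbouring genes with different name stems, 18 pairs changed the same way at 3 h. The mean of 10000 shuffles was 5.8 (permutation p = 3e-04). At 6 h 29 pairs did so, against 11.6 (permutation p = 1e-04, the smallest these shuffles can give). Another 4 and 18 pairs changed in opposite ways. The shuffles did not count such pairs, so clustering of called genes whatever their direction was not tested. They moved calls over all 18112 placed genes, dim ones included. An excess may therefore also reflect where expressed genes lie, which these shuffles cannot set apart. A general tendency of neighbours to vary together was tested on estradiol calls in control siRNA cells: 2 pairs against 0.9 at 3 h (permutation p = 0.22) and 12 against 2.8 at 6 h (permutation p = 1e-04, again the smallest). The bound set beforehand, a larger p of 0.05 or more counting against that tendency, was poorly chosen, since 0.9 expected pairs leave no room for a test at 3 h. That was decided after the result was seen; the 6 h value goes with a general tendency, so the 2 cannot be told apart.

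RAD21 siRNA in vehicle shifted estradiol-responsive genes by a little along their response on balance, with members on both sides. Over the 326 genes called for estradiol at 6 h, the RAD21 effect at 3 h had a median of 0.03 along the response, with 173 genes along it and 153 against, of which 47 and 13 were called. Over the 174 genes called at 3 h, the effect at 6 h had a median of 0.05, with 92 along and 82 against, of which 28 and 6 were called. The larger fry p was 0.00119 and the smaller 0.000622. In the fits without 1 vehicle array the fry p was 0.00819 or less. At 3 h the genes called against the response became 5, 6 and 6 without control vehicle replicate 1 or 3 or RAD21 siRNA vehicle replicate 1. They were 11 and 10 without control vehicle replicate 2 or RAD21 siRNA vehicle replicate 2. Without RAD21 siRNA vehicle replicate 3 they rose to 17, with 42 along and the highest fry p, 0.00819. At 6 h those called along and against became 17 and 3, 17 and 3, and 18 and 3 without control vehicle replicate 1, 2 or 3. Taken apart, genes raised and lowered by estradiol had a fry p of 0.0228 and 0.02 at 3 h (n = 201 and 125 genes) and of 0.0533 and 0.146 at 6 h (n = 125 and 49 genes), all along the response. The classical estradiol-repressed genes lay the other way, with medians of 0.145 at 3 h (11 of 17 higher) and 0.209 at 6 h (13 of 17 higher), short of the threshold (adjusted p = 0.118 and 0.0581, unadjusted 0.031 and 0.0275). At 6 h they passed upward with the mean of all probe sets (adjusted p = 0.0106) and without control vehicle replicate 3 (0.0201). The values over all called genes go with a small shift towards the estradiol-treated state. Some genes, such as AMIGO2 and S1PR3, share it, and others, such as MYC and IL20, go against it. Of the 17 classical repressed genes, 2 were called higher at each time and 1 was called lower at 3 h, so that list does not settle its direction. The arrays that chose the genes and those that measured the effect were different, but cultures may be shared between the times. Both contrasts subtract control vehicle, so a deviation shared by its arrays at both times would also give a shift along the response.

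Averaging over both time points in 1 fit of 24 arrays, the estradiol response differed between the siRNAs for 3 genes, KIF21A, CASTOR1 and USP31. At an unadjusted p under 0.05 there were 793 genes, fewer than the 907 expected by chance, so this number lends no support. The replicate block, with 6 genes, is the 1 alternative given for this fit, and its dependence on single arrays was not examined. The same fit called 0 genes at 3 h and 1 at 6 h, and the separate fits of 12 arrays called 0 at each time. Too few arrays at a single time point may be a part of the reason for a count of 0, but a fit of 24 arrays also has more residual freedom, and these were not tested apart.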
